A study of Cupriavidus necator with 17 samples.

How the data were processed

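RNA sequencing libraries of wild-type Cupriavidus necator grown on lactic acid at 37 °C were compared over 2 nitrogen sources and 3 times. Per the labels, RNA was extracted with a column kit, ribosomal RNA was removed and directional libraries were made with the dUTP method, with 17 libraries that the titles describe as biological replicates. The titles number the 2 libraries of ammonium nitrate at 12 h as replicates 1 and 2, while their library names carry the numbers 2 and 3.

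The table holds read counts per gene that the authors made by aligning reads with Bowtie2 and counting with featureCounts, whose versions, genome build and strand setting are not stated. Gene positions are given on 1 joined sequence, so no chromosome is printed, and lengths were not used in any test of a comparison. The same table holds FPKM values deposited by the authors; within a library each equals the count times 1 factor over gene length. Over genes with at least 100 counts, FPKM per count and kb times a DESeq2-style size factor varied by 2.25e-10 % between libraries, against 19.8 % times the library total, so the FPKM carry that scaling, which the labels do not state. Counts were used for all tests.

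Of 6893 genes, 6813 were coding, 15 were rRNA, 62 tRNA and 3 other RNA genes. The table gives a symbol for 1198 genes, and 164 more were named by the SwissProt entry given for this organism; 5531 have neither and are named by identifier and product. Library totals ran from 8017553 to 15767930 counts. Between the 16 pairs of libraries within groups, the squared difference over counting error alone had a chi-square per degree of freedom of 32.3 to 308, so spread between libraries lay above counting error in each pair; the correlation of log2 levels was 0.928 to 0.986.

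Counts were filtered with filterByExpr, which left 6674 genes, scaled by TMM and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 17 libraries entered 1 fit of 6 group means with no other covariate, since the labels do not say that replicate numbers pair libraries. Adjusted p is by Benjamini and Hochberg over the tested genes, with a threshold of 0.05; the number of genes changed at least 2-fold is given beside each count. The 9 comparisons were each later time against the one before within a source, ammonium nitrate against ammonium sulfate at each time, and the difference of each change over time between the sources.

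Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. The 22 lists, matched by symbol or product, were PHB synthesis and granules, PHB breakdown, lactate uptake and pyruvate entry, TCA and glyoxylate cycles, Calvin cycle, hydrogenases, nitrate and nitrite assimilation, nitrate respiration and denitrification, ammonium assimilation, sulfate uptake and cysteine synthesis, ribosomal proteins, ATP synthase, NADH dehydrogenase, terminal oxidases, flagella and chemotaxis, chaperones, oxidative stress defence, stationary phase, fatty acid beta-oxidation, iron uptake, type VI secretion and type IV pili. Each needed at least 5 tested members, and changed members were counted at adjusted p over all genes and over the list alone.

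Genes were named by a rule: the 5 largest rises and 5 largest falls of each comparison among passing genes with at least 50 CPM in the higher group, libraries that did not overlap and an informative product; up to 4 passing members with the largest change in each list described; and phaC, phaA, phaB, phaR, phaP1 and phaZ in each comparison. The rule for the differences in change used the size of the difference. Which of 4 genes named phaZ is phaZ1 is not given, so all 4 are reported.

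Levels are CPM, counts relative to TMM-scaled library size. Where a group had no counts, a floor of 3 counts over the group gave a lower bound; with 1 to 3 counts, a 95 % interval of the ratio was computed from the counts. Shares of rRNA were compared by two-sided exact permutation tests.

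Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups alone, RNA genes left out, the replicate number as a block (by title, by library number and nested in the source), each library left out in turn, and, for lists, an estimated correlation and fry. PHB gene levels were also taken without TMM and as FPKM. Where 1 library was left in a group, it was assumed to vary like the other groups. The tests, lists, naming rule and these alternatives were set before the data were examined. Further alternatives, named below, were added afterwards. The code was tested on simulated data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.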

Results

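RNA was sequenced from wild-type Cupriavidus necator, a bacterium that stores carbon as polyhydroxybutyrate (PHB), during fermentation on lactic acid at 37 °C. Cultures were fed 1 of 2 nitrogen sources and sampled at 12, 30 and 48 h. The sample titles call the first source ammonium nitrate, while the treatment field and the growth protocol call it ammonium nitrite; the name in the titles is used. The second source was ammonium sulfate. The 17 libraries formed 6 groups of 3 libraries, except that ammonium nitrate at 12 h had 2. Total counts over 6893 genes ran from 8017553 in ammonium nitrate 12 h replicate 2 to 15767930 in ammonium nitrate 48 h replicate 3. The comparisons address how gene expression changed with time and how it differed with the nitrogen source. Values after ± are standard errors beside log2 fold changes and standard deviations beside levels, which are in CPM (counts relative to library size), with n = 2 for ammonium nitrate at 12 h and n = 3 elsewhere. A gene is said to have risen or fallen where its adjusted p passed the threshold, and 6674 genes were tested. Changed members of gene lists are counted over all genes, and over the list alone where that number differs. In the comparisons of 1 group with another, the libraries did not overlap for the genes with the largest rises and falls. The first principal component held 41.3 % of the variance between libraries and the second 21.3 %.

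**Figure D1:**
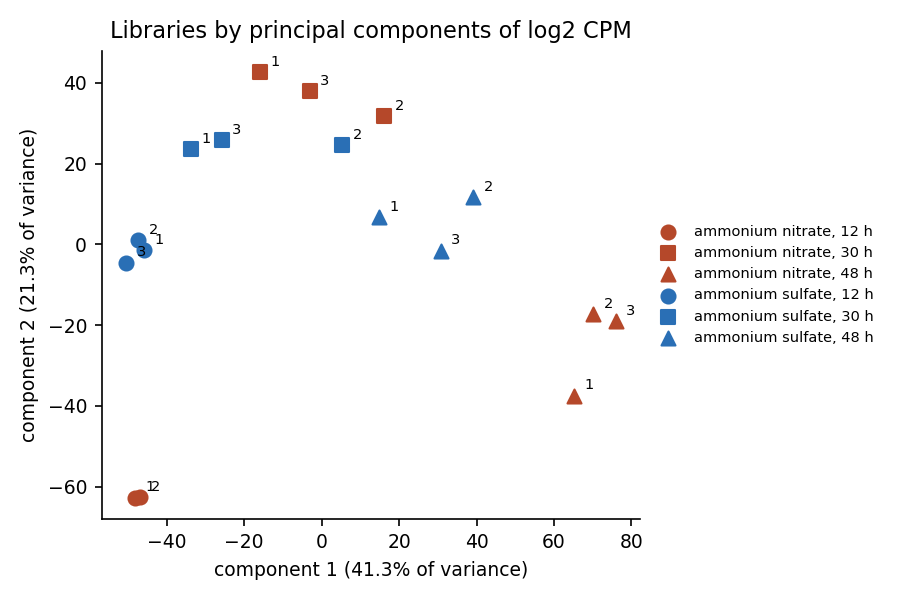
The 17 libraries on the first 2 principal components of log2 CPM, with colour for the nitrogen source, marker shape for the time and numbers for the replicates. The 48 h ammonium nitrate libraries lie at the far end of the first component, and the 30 h libraries numbered 2 of both sources have higher values on that component than the other 30 h libraries of their source.

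Between 12 and 30 h in ammonium nitrate, nitrate respiration and denitrification genes fell as a list, and nitrogen control genes rose and flagella genes fell without passing with an estimated correlation (adjusted p = 0.171 and 0.128). The ammonium transporter amt (H16_RS01580) rose from 8.31 ± 1.64 to 1126 ± 615, a log2 fold change of 7.08 ± 0.59 (adjusted p = 3.99e-07). The assimilatory nitrite reductase gene nirB (H16_RS22625) rose by 7.21 ± 1.13, the nitrate transporter permease gene ntrB (H16_RS01760) by 7.07 ± 1.60 and the MFS transporter H16_RS22630 by 7.02 ± 1.18. The largest rise was that of H16_RS06740, an acetyl-CoA hydrolase/transferase family gene, at 7.32 ± 2.13, with a widely spread 30 h level of 2846 ± 2763. The H16_RS06740 call ended without ammonium nitrate 12 h replicate 1 or 2 (adjusted p from 0.0887 to 0.103). The large subunit gene of nitric oxide reductase, H16_RS30305, fell from 835 ± 107 to 3.90 ± 2.22, a log2 fold change of -7.77 ± 0.44 (adjusted p = 6.32e-09). Falls of similar size were seen for the peptidylprolyl isomerase gene H16_RS30035 (-8.67 ± 0.70), the flagellar export gene fliI (H16_RS30540, -7.52 ± 0.58) and the copper genes H16_RS29615 (-6.82 ± 0.60) and copC (H16_RS29610, -6.78 ± 0.60).

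By gene list, 18 of 33 ammonium assimilation and nitrogen control genes rose and 2 fell (median 2.17, list adjusted p = 1.1e-08, adjusted p = 0.171 with an estimated correlation), among them the urea transporter genes urtB (H16_RS05350, 6.99 ± 0.64) and urtD (H16_RS05360, 6.83 ± 0.60). Of the 22 nitrate respiration and denitrification genes, 13 fell and 6 rose (median -4.02, list adjusted p = 6.22e-08, passing too at adjusted p = 0.0181 with an estimated correlation). The nitrate reductase gene narI (H16_RS30030) had no counts at 30 h and was at least 27.3-fold lower, against a floor of 3 counts over the group; such floors and the intervals cover counting error only. The second narI gene, H16_RS32835, was 291-fold lower (95 % counting interval 79.9 to 2409). Flagella and chemotaxis genes fell in 49 of 78 cases and rose in 4 (median -2.23, list adjusted p = 5.89e-16, adjusted p = 0.128 with an estimated correlation), with fliH (H16_RS30535) at -7.05 ± 0.75 and fliG (H16_RS30530) at -6.97 ± 0.71. Over the flagella list alone, 52 fell and 4 rose. Ribosomal protein genes fell in 47 of 59 cases and none rose (median -1.62, list adjusted p = 3.81e-11, adjusted p = 0.544 with an estimated correlation), as for rplD (H16_RS17375, -2.74 ± 0.55) and rplN (H16_RS17330, -2.69 ± 0.51). Adjusted over the ribosomal list alone, 50 fell and none rose. In replicate 2 at 30 h, the median gene departed from the other 30 h replicates by -0.51 for ribosomal proteins, -0.58 for the ammonium list and -0.76 for the Calvin cycle list. Stationary phase genes rose in 16 of 27 cases and fell in 1 (median 1.44, list adjusted p = 2.39e-06, adjusted p = 0.237 with an estimated correlation), led by universal stress protein genes such as H16_RS25865 (4.62 ± 0.94) and H16_RS25860 (4.21 ± 0.57). In the stationary phase list alone, 20 rose and 3 fell. Fatty acid beta-oxidation genes rose in 44 of 139 cases and fell in 9 (median 0.55, list adjusted p = 0.0108, adjusted p = 0.173 with an estimated correlation), with H16_RS09420 up by 4.44 ± 0.83 and H16_RS09400 by 3.67 ± 0.86. Over the beta-oxidation list alone, 43 rose and 9 fell. Of the 16 NADH dehydrogenase genes, 7 fell and none rose (median -0.66, list adjusted p = 0.0273, adjusted p = 0.718 with an estimated correlation), H16_RS05220 at -1.93 ± 0.32; the median gene departed by -0.51 in replicate 2. Adjusted over the NADH dehydrogenase list alone, 8 fell and none rose. The NADH dehydrogenase list missed the threshold without ammonium nitrate 12 h replicate 1 or 30 h replicate 2 (adjusted p from 0.0526 to 0.0891). The Calvin cycle list had 6 tested members, of which 4 were subunit genes of the cbb3 oxidase, a respiratory enzyme; 4 rose (median 2.66, list adjusted p = 0.00219, adjusted p = 0.173 with an estimated correlation), including ccoN (H16_RS11590, 3.79 ± 0.53) and ccoP (H16_RS11575, 3.37 ± 0.51).

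In total 2620 genes changed, 1301 up and 1319 down, of which 2108 changed at least 2-fold. The other 14 lists did not pass (adjusted p from 0.151 to 0.929), among them oxidative stress defence with 5 of 25 genes up and 3 down (median 0.40, list adjusted p = 0.427), where the superoxide dismutase gene sodB (H16_RS03015) fell by 2.64 ± 0.24 and the catalase gene H16_RS15510 rose by 2.63 ± 0.36. Without ammonium nitrate 12 h replicate 1 or 2, leaving 1 library in that group, the count was 1371 or 1608.

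Between 30 and 48 h in ammonium nitrate, nitrate respiration and denitrification genes fell as a list. The lactate permease gene H16_RS19175 fell from 3879 ± 1864 to 3.89 ± 1.79, a change of -9.98 ± 0.64 (adjusted p = 6.38e-09). With the next locus numbers, the lactate oxidation gene H16_RS19180 fell by 8.86 ± 0.69 and H16_RS19185 by 8.67 ± 0.69. The ABC transporter gene H16_RS32720 and the nitrous oxide reductase maturation gene H16_RS32725 fell by 8.42 ± 0.42 and by 7.95 ± 0.49. The CoA-transferase gene H16_RS29745 rose from 17.9 ± 4.04 to 780.4 ± 220.4, a log2 fold change of 5.45 ± 0.40 (adjusted p = 2.69e-08). The acetoin dehydrogenase genes acoA (H16_RS19450), acoB (H16_RS19455) and acoC (H16_RS19460) rose by 5.19 ± 1.24, 5.43 ± 1.07 and 5.08 ± 1.08, and the aconitate hydratase gene acnB (H16_RS21565) by 5.23 ± 0.69.

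Of the 22 nitrate respiration and denitrification genes, 13 fell and none rose (median -2.21, list adjusted p = 7.12e-14, passing too at adjusted p = 0.00209 with an estimated correlation); nosZ (H16_RS32735), which encodes nitrous oxide reductase, fell from 14041 ± 5704 to 75.4 ± 23.5, and narH (H16_RS32825) had no counts at 48 h and was at least 8.70-fold lower. Adjusted over the denitrification list alone, 14 fell and none rose. Lactate uptake and pyruvate entry genes fell in 6 of 14 cases (median -0.53, or 0.13 without scaling, list adjusted p = 2.38e-05, adjusted p = 0.0694 with an estimated correlation), including ldh (H16_RS03295, -6.13 ± 0.48) and the pyruvate dehydrogenase genes aceE (H16_RS06820, -3.74 ± 0.46) and aceF (H16_RS06825, -3.93 ± 0.46). In the lactate list alone, 6 fell and 1 rose. Stationary phase genes fell in 17 of 27 cases and rose in 2 (median -1.22, list adjusted p = 4.07e-09, adjusted p = 0.0998 with an estimated correlation), with the universal stress protein gene H16_RS25855 at -6.15 ± 0.61. Over the stationary phase list alone, 19 fell and 2 rose. PHB synthesis and granule genes fell in 7 of 13 cases (median -1.14, list adjusted p = 8.38e-05, adjusted p = 0.0998 with an estimated correlation), led by the phasin gene phaP2 (H16_RS32515, -4.81 ± 0.38) and the acetoacetyl-CoA reductase gene phbB (H16_RS09985, -4.76 ± 0.51). Adjusted over the PHB synthesis list alone, 9 fell and none rose. NADH dehydrogenase genes fell in 14 of 16 cases (median -0.91, list adjusted p = 0.00169, adjusted p = 0.595 with an estimated correlation) and ATP synthase genes in 7 of 9 (median -1.54, list adjusted p = 0.00278, adjusted p = 0.595 with an estimated correlation), with atpD (H16_RS18160) at -1.59 ± 0.35; in replicate 2 at 30 h the median gene of the ATP synthase, NADH dehydrogenase and Calvin cycle lists departed from the other replicates by -1.26, -0.51 and -0.76. Over the ATP synthase list alone, 8 fell and none rose. Terminal oxidase genes fell in 7 of 29 cases and rose in 1 (median -0.28, or 0.36 without scaling, list adjusted p = 0.0112, adjusted p = 0.279 with an estimated correlation), with ccoG (H16_RS11570) at -4.67 ± 0.40. Of the Calvin cycle list, mostly cbb3 oxidase genes, 5 of 6 fell (median -2.48, list adjusted p = 3.74e-05, adjusted p = 0.0623 with an estimated correlation), ccoP (H16_RS11575) at -4.84 ± 0.46. Hydrogenase genes rose in 20 of 47 cases and fell in 1 (median 0.61, list adjusted p = 0.0215, adjusted p = 0.808 with an estimated correlation), with hypB (H16_RS31970) up by 1.54 ± 0.27; the fall (fdhD, H16_RS03180) and 2 rises (fdhE and H16_RS14615) were of formate dehydrogenase accessory genes, singled out after their values were seen. Over the hydrogenase list alone, 20 rose and 2 fell. The hydrogenase list did not pass without ammonium nitrate 48 h replicate 2 or 3 (adjusted p from 0.0864 to 0.127). Sulfate uptake and cysteine synthesis genes rose in 9 of 26 cases and fell in 3 (median 0.17, list adjusted p = 0.0366, adjusted p = 0.595 with an estimated correlation), including cysW (H16_RS11185, 4.79 ± 0.63) and cysT (H16_RS11190, 4.60 ± 0.54). The sulfate list missed the threshold without ammonium nitrate 30 h replicate 2 or 3 or 48 h replicate 1 (adjusted p from 0.054 to 0.0786).

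From 30 to 48 h 2000 genes changed in ammonium nitrate, 1016 up and 984 down, and 1473 of them at least 2-fold. The other 12 lists did not pass (adjusted p from 0.125 to 0.98); in the type VI secretion list 2 of 30 genes rose and 5 fell (median 0.39, list adjusted p = 0.826), with tssI (H16_RS29230) at -5.92 ± 0.35. Changes are relative to TMM scaling; unscaled CPM moved the median of all genes by 0.64 here, by 0.30 between the same times in ammonium sulfate, and by -0.30 to 0.34 in the other comparisons.

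In ammonium sulfate between 12 and 30 h, ammonium assimilation and nitrogen control genes rose as a list. The CmpA/NrtA family transporter gene H16_RS01765 rose by 8.57 ± 1.33, ntrB (H16_RS01760) by 8.15 ± 1.45 and amt (H16_RS01580) from 4.23 ± 0.493 to 848 ± 88.6, a log2 fold change of 7.64 ± 0.51 (adjusted p = 1.3e-07). The nitrogen regulator gene H16_RS01575 of the P-II family rose by 7.30 ± 0.62 and the porin gene H16_RS01570 by 7.43 ± 0.68. The amino acid transporter gene H16_RS26885 fell from 633 ± 314 to 11.5 ± 0.231, a change of -5.78 ± 0.47 (adjusted p = 1.26e-06). Sulfur genes made up the other largest falls: phosphoadenylyl-sulfate reductase (H16_RS14940, -4.89 ± 0.76), nitrite/sulfite reductase (H16_RS14950, -4.78 ± 0.69), cysD (H16_RS14935, -4.70 ± 0.69) and the exporter H16_RS14955 (-4.66 ± 0.69).

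Of the 33 ammonium assimilation and nitrogen control genes, 18 rose and none fell (median 1.45, list adjusted p = 4.64e-25, passing too at adjusted p = 0.0149 with an estimated correlation), with urtB (H16_RS05350) up by 6.27 ± 0.52. Over the ammonium list alone, 18 rose and 2 fell. Sulfate uptake and cysteine synthesis genes fell in 9 of 26 cases and rose in 1 (median -0.39, list adjusted p = 3.08e-07, adjusted p = 0.118 with an estimated correlation). Adjusted over the sulfate list alone, 9 fell and 2 rose. Nitrate and nitrite assimilation genes rose in 4 of 7 cases (median 1.83, list adjusted p = 0.0036, adjusted p = 0.23 with an estimated correlation), with nirB (H16_RS22625) up by 6.24 ± 0.89; in replicate 2 the median gene of this list departed from the other 30 h replicates by 2.46. Ribosomal protein genes fell in 26 of 59 cases (median -1.28, list adjusted p = 4.64e-25, adjusted p = 0.167 with an estimated correlation), rpsB (H16_RS10255) at -1.67 ± 0.40, and the median gene departed by -0.72 in replicate 2. Over the ribosomal list alone, 52 fell and none rose. The rpsB call ended without ammonium sulfate 12 h replicate 3 (adjusted p = 0.0664). NADH dehydrogenase genes fell in 12 of 16 cases (median -1.02, list adjusted p = 5.65e-11, adjusted p = 0.156 with an estimated correlation) and ATP synthase genes in 8 of 9 (median -1.30, list adjusted p = 4.86e-08, adjusted p = 0.165 with an estimated correlation), with nuoH (H16_RS05255) at -1.21 ± 0.24; their medians in replicate 2 departed by -0.58 and -0.88, and those of the ammonium, stationary phase and TCA lists by 0.54, 0.62 and -0.51. Adjusted over the NADH dehydrogenase list alone, 14 fell and none rose. In the ATP synthase list alone, 9 fell and none rose. Terminal oxidase genes fell in 7 of 29 cases (median -0.41, list adjusted p = 3.98e-05, adjusted p = 0.13 with an estimated correlation), led by cyoA (H16_RS05325, -1.33 ± 0.22). Over the terminal oxidase list alone, 11 fell and none rose. Beta-oxidation genes rose in 9 of 139 cases (median 0.34, list adjusted p = 0.00686, adjusted p = 0.156 with an estimated correlation), with the ligase gene H16_RS13930 up by 1.39 ± 0.29. Iron uptake and siderophore genes rose in 4 of 28 cases (median 0.78, list adjusted p = 0.0351, adjusted p = 0.456 with an estimated correlation), the receptor gene H16_RS31520 by 2.04 ± 0.33, and the median gene departed by -1.19 in replicate 2. In the iron uptake list alone, 6 rose and none fell. The iron uptake list missed the threshold without ammonium sulfate 12 h replicate 3 or 30 h replicate 1 or 3 (adjusted p from 0.063 to 0.169). Stationary phase genes rose in 1 of 27 cases (median 0.63, list adjusted p = 0.00686, adjusted p = 0.456 with an estimated correlation), and TCA and glyoxylate cycle genes rose in 2 and fell in 1 of 31 cases (median -0.53, list adjusted p = 0.0382, adjusted p = 0.552 with an estimated correlation). Over the stationary phase list alone, none passed. The stationary phase list did not pass without ammonium sulfate 30 h replicate 2 (adjusted p = 0.128). Adjusted over the TCA cycle list alone, 2 fell and 2 rose. The TCA cycle list missed the threshold without ammonium sulfate 12 h replicate 2 or 30 h replicate 2 (adjusted p from 0.0722 to 0.454). The TCA list held 3 isopropylmalate genes of leucine synthesis, of which leuA (H16_RS19130) rose by 1.27 ± 0.27. The leuA call ended without ammonium sulfate 12 h replicate 3 (adjusted p = 0.0605). With no member called, the Calvin cycle list passed as well (median -1.10, list adjusted p = 0.031, adjusted p = 0.267 with an estimated correlation). In the Calvin cycle list alone, 3 fell and none rose. The Calvin cycle list did not pass without ammonium sulfate 12 h replicate 2 or 30 h replicate 1 (adjusted p from 0.0661 to 0.0729).

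Over the whole comparison 589 genes changed, 291 up and 298 down, with 465 at least 2-fold. The other 10 lists did not pass (adjusted p from 0.0586 to 0.761); among PHB breakdown genes 3 of 14 rose (median 0.46, list adjusted p = 0.0586, passing without ammonium sulfate 12 h replicate 3 or 30 h replicate 1). Over the PHB breakdown list alone, 3 rose and 1 fell. Without ammonium sulfate 12 h replicate 1, 2 or 3 the count was 267, 276 or 229, and with DESeq2 it was 919.

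Between 30 and 48 h in ammonium sulfate, the CoA-transferase gene H16_RS29745 rose from 14.1 ± 4.15 to 689 ± 294, a log2 fold change of 5.61 ± 0.40 (adjusted p = 7.62e-07), as it did in ammonium nitrate. The acetoin genes acoB (H16_RS19455) and acoC (H16_RS19460) rose by 4.63 ± 1.02 and 4.78 ± 1.06. The rises were 4.69 ± 1.13 for acoX (H16_RS19445) and 4.63 ± 1.19 for acoA (H16_RS19450). The calls for acoX (adjusted p from 0.0592 to 0.0786) and acoA (adjusted p from 0.0738 to 0.085) ended without ammonium sulfate 30 h replicate 1 or 3 or 48 h replicate 2. The largest falls were in genes lying close together by locus number, the peptide synthetase gene H16_RS27155 (-5.86 ± 1.40), the hydrolase gene H16_RS27170 (-5.43 ± 1.41), the acetyltransferase gene H16_RS27125 (-5.39 ± 1.28) and the dioxygenase gene H16_RS27160 (-5.38 ± 1.31), and in the phosphopantetheinyl transferase gene H16_RS33800 (-5.37 ± 1.40). The calls for H16_RS27155 (adjusted p from 0.0643 to 0.0651) and H16_RS27160 (adjusted p from 0.0658 to 0.0665) ended without ammonium sulfate 48 h replicate 2 or 3. The calls for H16_RS27170 (adjusted p from 0.0592 to 0.0769) and H16_RS33800 (adjusted p from 0.0594 to 0.0849) ended without ammonium sulfate 30 h replicate 1 or 3 or 48 h replicate 1, 2 or 3. The H16_RS27125 call ended without ammonium sulfate 30 h replicate 1 or 48 h replicate 2 or 3 (adjusted p from 0.058 to 0.0645).

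Chaperone and heat shock genes fell in 6 of 22 cases (median -0.67, list adjusted p = 2.89e-04, adjusted p = 0.505 with an estimated correlation); the chaperonin gene groL (H16_RS03495) fell from 10096 ± 11630 to 257 ± 219 and groES (H16_RS03490) by 5.15 ± 0.96. Adjusted over the chaperone list alone, 10 fell and none rose. NADH dehydrogenase genes fell in 6 of 16 cases (median -0.66, list adjusted p = 9.68e-05, adjusted p = 0.505 with an estimated correlation) and denitrification genes in 5 of 22 (median -1.08, or -0.96 with members at 0 counts set to their bound, list adjusted p = 1.31e-04, adjusted p = 0.0954 with an estimated correlation), including ytfE (H16_RS32700, -1.76 ± 0.32) and nirJ (H16_RS30105, -1.65 ± 0.30). In the NADH dehydrogenase list alone, 12 fell and none rose. Over the denitrification list alone, 9 fell and 1 rose. The ammonium list rose in 3 and fell in 8 of 33 cases (median -0.27, or 0.02 without scaling, list adjusted p = 0.0164, adjusted p = 0.516 with an estimated correlation), with gdhA (H16_RS28460), a glutamate dehydrogenase gene, at -3.03 ± 0.53 and ntrC (H16_RS11655), a regulator of nitrogen metabolism, at -2.02 ± 0.38. Adjusted over the ammonium list alone, 4 rose and 8 fell. The ammonium list missed the threshold without ammonium sulfate 30 h replicate 2 or 48 h replicate 1 (adjusted p from 0.0879 to 0.128). Iron uptake genes fell in 8 of 28 cases (median -1.02, list adjusted p = 0.0164, adjusted p = 0.516 with an estimated correlation), and PHB synthesis genes in 3 of 13 (median -0.64, list adjusted p = 0.032, adjusted p = 0.505 with an estimated correlation). In the iron uptake list alone, 9 fell and none rose. The iron uptake list did not pass without ammonium sulfate 30 h replicate 3 or 48 h replicate 1 (adjusted p from 0.0523 to 0.0736). The PHB synthesis list missed the threshold without ammonium sulfate 30 h replicate 2 or 48 h replicate 3 (adjusted p from 0.175 to 0.237). Ribosomal protein genes fell in 1 of 59 cases (median -0.54, list adjusted p = 9.94e-06, adjusted p = 0.554 with an estimated correlation). Adjusted over the ribosomal list alone, none passed. Hydrogenase genes rose in 7 of 47 cases and fell in 2 (median 0.43, list adjusted p = 0.00855, adjusted p = 0.523 with an estimated correlation). In the hydrogenase list alone, 12 rose and 2 fell. The hydrogenase list missed the threshold without ammonium sulfate 30 h replicate 1 (adjusted p = 0.0935). Both falls, xdhA (H16_RS05055) and fdhD (H16_RS03180), and 1 rise, fdhE (H16_RS25980), were of xanthine and formate dehydrogenase genes. The xdhA call ended without ammonium sulfate 30 h replicate 1 or 48 h replicate 1, 2 or 3 (adjusted p from 0.0607 to 0.209). The fdhD call ended without ammonium sulfate 30 h replicate 1 or 48 h replicate 2 or 3 (adjusted p from 0.0629 to 0.151). The fdhE call ended without ammonium sulfate 30 h replicate 3 or 48 h replicate 2 (adjusted p from 0.0587 to 0.0717). Of the nitrate assimilation genes only cynS (H16_RS18950), for cyanase, rose, by 2.78 ± 0.53, of 7 tested (median 1.55, list adjusted p = 0.0366, adjusted p = 0.505 with an estimated correlation). The nitrate assimilation list did not pass without ammonium sulfate 30 h replicate 3 or 48 h replicate 1 (adjusted p from 0.0628 to 0.102). The TCA list had 2 of 31 genes down (median -0.40, list adjusted p = 0.0265, adjusted p = 0.554 with an estimated correlation), and in the type VI secretion list 1 of 30 genes rose (median 0.48, list adjusted p = 0.0265, adjusted p = 0.505 with an estimated correlation). The TCA cycle list missed the threshold without ammonium sulfate 30 h replicate 1 or 3 or 48 h replicate 3 (adjusted p from 0.0557 to 0.0987). In the type VI secretion list alone, none passed. The type VI secretion list did not pass without ammonium sulfate 30 h replicate 1 or 48 h replicate 1 (adjusted p from 0.137 to 0.245). In replicate 2 at 30 h the median gene departed from the other 30 h replicates by 2.46 for nitrate assimilation, -1.19 for iron uptake, -0.72 for ribosomal proteins, -0.58 for NADH dehydrogenase, -0.52 for chaperones, -0.51 for the TCA list, 0.56 for hydrogenases and 0.54 for the ammonium list.

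These 808 changed genes split into 356 up and 452 down, 588 of them at least 2-fold, and the other 11 lists did not pass (adjusted p from 0.0585 to 0.986). Without ammonium sulfate 30 h replicate 1, 2 or 3 the count was 263, 1563 or 335, and without 48 h replicate 2 or 3 it was 271 or 308. Without both 30 h libraries numbered 2 it was 1712, and with only the compared groups in the fit 129.

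The sources shared many changes over time. From 12 to 30 h, 198 genes rose in both, where 56.7 would be shared if the calls were independent, and 181 fell in both against 58.9. From 30 to 48 h the shared numbers were 262 up against 54.2 and 314 down against 66.6. Across genes, which are not independent replicates, the log2 fold changes of the sources correlated at Pearson 0.524 and Spearman 0.505 for the earlier interval and at 0.635 and 0.64 for the later one.

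**Figure D2:**
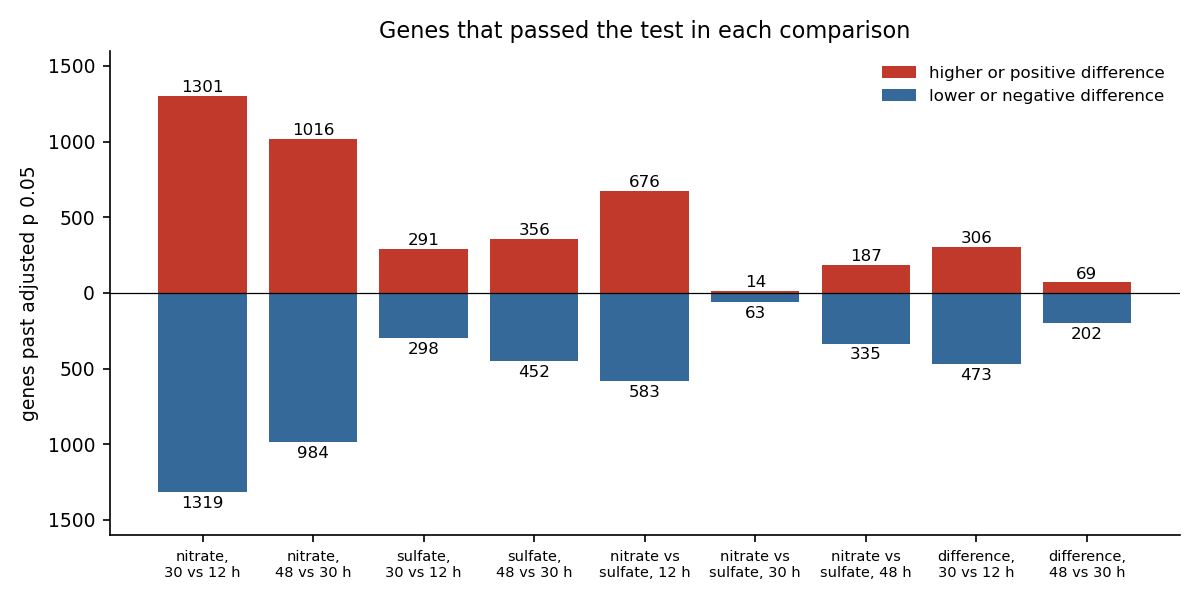
Number of genes that rose (above 0) and fell (below 0) in each of the 9 comparisons of 6674 genes. Most genes changed between 12 and 30 h in ammonium nitrate, 2620, and fewest differed between the sources at 30 h, 77.

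At 12 h, cells in ammonium nitrate had higher levels of denitrification, nitrate respiration and flagellar genes than cells in ammonium sulfate. The nitric oxide reductase gene H16_RS30305 stood at 835 ± 107 against 1.92 ± 0.905, a log2 difference of 8.76 ± 0.46 (adjusted p = 3.67e-09). The carbonic anhydrase gene H16_RS30040 was higher by 8.09 ± 0.88, the peptidylprolyl isomerase genes H16_RS30035 and H16_RS32840 by 7.80 ± 0.65 and 7.60 ± 0.61, and the flagellar rod gene flgF (H16_RS20060) by 7.22 ± 0.65. Lower in ammonium nitrate were ccoN (H16_RS11590), at 359 ± 25.4 against 7489 ± 350.1 (log2 difference -4.38 ± 0.55), the amino acid transporter gene H16_RS26885 (-5.59 ± 0.55) and the MFS transporter gene H16_RS08695 (-4.48 ± 0.69). So were H16_RS06740 (-6.88 ± 2.09) and groL (H16_RS03495, -4.60 ± 1.24). The H16_RS06740 call ended without ammonium nitrate 12 h replicate 1 or 2 or ammonium sulfate 12 h replicate 1 (adjusted p from 0.0519 to 0.188). The groL call ended without ammonium nitrate 12 h replicate 1 or 2 (adjusted p from 0.119 to 0.144).

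Of the 22 denitrification genes 13 were higher and 3 lower in ammonium nitrate (median 4.45, list adjusted p = 1.12e-16, passing too at adjusted p = 0.0011 with an estimated correlation). Over the denitrification list alone, 13 were higher and 5 were lower. The genes narJ (H16_RS30025) and narH (H16_RS30020) had no counts in ammonium sulfate and were at least 100.9-fold and 71.3-fold higher. Flagella and chemotaxis genes were higher in 42 of 78 cases and lower in 4 (median 1.58, list adjusted p = 1.42e-24, passing too at adjusted p = 0.0319 with an estimated correlation), with fliG (H16_RS30530) at 7.21 ± 0.72 and flgH (H16_RS20070) at 6.69 ± 0.61. Adjusted over the flagella list alone, 50 were higher and 4 were lower. The nitrate transporter gene H16_RS30005 was 121-fold higher (95 % counting interval 40.9 to 591) within a list of 7 nitrate assimilation genes, 2 higher and 1 lower (median 0.62, list adjusted p = 0.0868). Ribosomal protein genes were lower in 23 of 59 cases (median -0.94, list adjusted p = 5.83e-09, adjusted p = 0.58 with an estimated correlation), and chaperone genes in 13 of 22 (median -1.76, list adjusted p = 4.98e-06, adjusted p = 0.33 with an estimated correlation), such as H16_RS07065 and H16_RS07070 of the Hsp20 family (-4.10 ± 0.68 and -3.75 ± 0.66). Over the ribosomal list alone, 24 were lower and none higher. Adjusted over the chaperone list alone, 14 were lower and none higher. Mainly through cbb3 oxidase genes, the Calvin cycle list was lower in 4 of 6 cases (median -3.02, list adjusted p = 4.98e-06, passing too at adjusted p = 0.0475 with an estimated correlation), and terminal oxidase genes in 6 of 29 (median -0.34, list adjusted p = 0.00553, adjusted p = 0.33 with an estimated correlation), ccoO (H16_RS11585) at -4.11 ± 0.61. Over the terminal oxidase list alone, 6 were lower and 1 was higher. Stationary phase genes were lower in 8 of 27 cases and higher in 1 (median -0.71, list adjusted p = 0.00767, adjusted p = 0.58 with an estimated correlation), H16_RS11100 at -2.46 ± 0.48. Adjusted over the stationary phase list alone, 10 were lower and 2 were higher. Sulfate uptake genes were lower in 10 of 26 cases and higher in 1 (median -0.92, list adjusted p = 0.0066, adjusted p = 0.336 with an estimated correlation), cysT (H16_RS11190) at -3.16 ± 0.59. In the sulfate list alone, 12 were lower and 1 was higher. The TCA list was lower in 6 of 31 cases (median -0.39, list adjusted p = 0.00792, adjusted p = 0.58 with an estimated correlation), with aceA (H16_RS11130), isocitrate lyase of the glyoxylate cycle, at -4.13 ± 0.75. Over the TCA cycle list alone, 9 were lower and none higher. NADH dehydrogenase genes were lower in 2 of 16 cases (median -0.55, list adjusted p = 0.00858, adjusted p = 0.593 with an estimated correlation). Adjusted over the NADH dehydrogenase list alone, 5 were lower and none higher.

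At this time 1259 genes differed, 676 higher and 583 lower in ammonium nitrate, with 1022 at least 2-fold apart, and the other 12 lists did not pass (adjusted p from 0.0868 to 0.986). Without ammonium nitrate 12 h replicate 1 or 2 the count was 547 or 528, and from a fit of the 12 h libraries alone it was 2637.

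At 30 h the fewest genes differed, most lower in ammonium nitrate. That balance changed without ammonium sulfate replicate 2 (230 higher, 240 lower) or both libraries numbered 2 (98 and 94). The median absolute log2 difference, 0.325, was near the 0.337 at 48 h. The methyltransferase gene H16_RS02965 stood at 31.7 ± 15.7 against 428 ± 383, a log2 difference of -3.75 ± 0.51 (adjusted p = 0.00157). The helicase gene H16_RS13440 was lower, at -2.92 ± 0.40, infA (H16_RS28350), for translation initiation factor IF-1, at -2.64 ± 0.36, and edd (H16_RS05850), for the Entner-Doudoroff dehydratase, at -2.37 ± 0.34. The protease gene H16_RS19525 was lower, at -2.42 ± 0.47 and the pilus gene H16_RS04860 higher by 3.51 ± 0.62. The H16_RS19525 call ended without ammonium nitrate 30 h replicate 1, 2 or 3 or ammonium sulfate 30 h replicate 1 (adjusted p from 0.0655 to 0.145). The H16_RS04860 call ended without ammonium nitrate 30 h replicate 3 or ammonium sulfate 30 h replicate 1 (adjusted p from 0.0688 to 0.0789). Also higher were the sterol-binding domain gene H16_RS30330 (1.41 ± 0.33), the saccharopine dehydrogenase domain gene H16_RS16685 (1.40 ± 0.30) and the flagellar regulator gene flhC (H16_RS23335, 1.08 ± 0.20). The H16_RS30330 call ended without ammonium nitrate 30 h replicate 1, 2 or 3 or ammonium sulfate 30 h replicate 1 or 3 (adjusted p from 0.0829 to 0.274). The calls for H16_RS16685 (adjusted p from 0.073 to 0.235) and flhC (adjusted p from 0.0628 to 0.0978) ended without ammonium nitrate 30 h replicate 2 or 3 or ammonium sulfate 30 h replicate 1 or 3. Ribosomal protein genes were lower in 15 of 59 cases (median -1.41, list adjusted p = 3.04e-48, adjusted p = 0.29 with an estimated correlation); rplJ (H16_RS17455) was lower, at -2.18 ± 0.36. In the ribosomal list alone, 52 were lower and none higher. The rplJ call ended without ammonium nitrate 30 h replicate 3 (adjusted p = 0.0688). With no member called, lists for stationary phase (median 0.54, list adjusted p = 0.0032, adjusted p = 0.595 with an estimated correlation), chaperones (median -0.40, list adjusted p = 0.00577, adjusted p = 0.595 with an estimated correlation), NADH dehydrogenase (median -0.34, list adjusted p = 0.0342, adjusted p = 0.655 with an estimated correlation), nitrate assimilation (median 0.49, list adjusted p = 0.0342, adjusted p = 0.595 with an estimated correlation) and the TCA cycle (median -0.31, list adjusted p = 0.0342, adjusted p = 0.655 with an estimated correlation) also passed. The chaperone list did not pass without ammonium sulfate 30 h replicate 1 (adjusted p = 0.319). The NADH dehydrogenase list missed the threshold without ammonium nitrate 30 h replicate 2 or ammonium sulfate 30 h replicate 1 or 3 (adjusted p from 0.0771 to 0.345). The nitrate assimilation list did not pass without ammonium nitrate 30 h replicate 1 or 3 or ammonium sulfate 30 h replicate 1 or 3 (adjusted p from 0.0536 to 0.2). The TCA cycle list missed the threshold without ammonium nitrate 30 h replicate 2 or 3 or ammonium sulfate 30 h replicate 1 or 3 (adjusted p from 0.0571 to 0.486). In replicate 2 of ammonium nitrate and of ammonium sulfate the median gene departed from the other replicates by -0.51 and -0.72 for ribosomal proteins, -0.25 and 0.62 for stationary phase, 0.04 and -0.52 for chaperones, -0.51 and -0.58 for NADH dehydrogenase, 0.15 and 2.46 for nitrate assimilation, and -0.56 and -0.51 for the TCA list. Of the 44 type IV pilus genes 4 were higher (median 0.08, list adjusted p = 0.211), H16_RS04880 by 2.98 ± 0.48. In the type IV pilus list alone, 4 were higher and 1 was lower.

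Here 77 genes differed, 14 higher and 63 lower, 73 of them at least 2-fold, and the other 16 lists did not pass (adjusted p from 0.0705 to 0.997). The count was 39, 23 or 13 without ammonium nitrate 30 h replicate 1, 2 or 3, and 19, 470 or 45 without the ammonium sulfate ones; with the replicate number as a block it was 100, or 47 in a fit of the 30 h libraries alone, which without the block gave 15, and with DESeq2 it was 236. In the blocked fit of these libraries 8 of 16 named genes did not pass (adjusted p from 0.0595 to 0.204): H16_RS02965, H16_RS19525, H16_RS30330, H16_RS16685, flhC, rplJ and the pilus genes cpaB (H16_RS04875) and H16_RS04905.

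**Figure D3:**
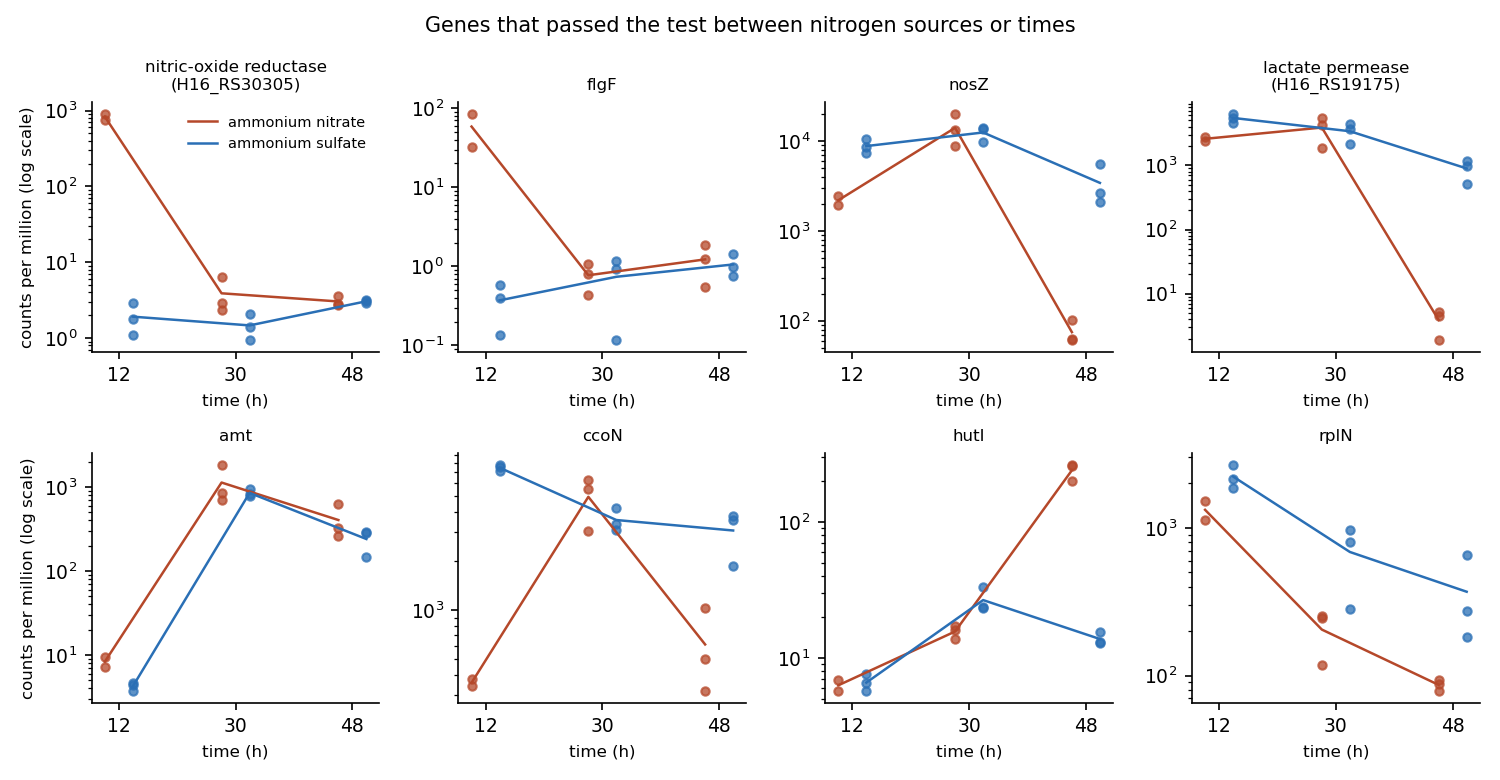
CPM on a log axis at 12, 30 and 48 h for 8 genes; points are libraries, lines join group means, and colour gives the nitrogen source. H16_RS30305 is high only at 12 h in ammonium nitrate, and H16_RS19175 and nosZ are lowest at 48 h in ammonium nitrate.

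At 48 h, denitrification and lactate genes were lower as lists in ammonium nitrate. The imidazolonepropionase gene hutI (H16_RS15030) stood at 240.2 ± 35.7 against 13.8 ± 1.41, a log2 difference of 4.12 ± 0.23 (adjusted p = 8.56e-09). Close by, H16_RS15025 and H16_RS15035 were higher by 4.08 ± 0.27 and 4.07 ± 0.26, and elsewhere the aldolase gene H16_RS09455 and the nitrogen starvation response gene H16_RS09755 by 4.01 ± 0.72 and 3.83 ± 0.69. The lactate permease gene H16_RS19175 stood at 3.89 ± 1.79 against 894 ± 346 (-7.87 ± 0.59, adjusted p = 7.92e-08). Lower too were H16_RS19180 (-6.96 ± 0.64), the CoA ester lyase gene H16_RS29255 (-6.90 ± 0.76), the tricarboxylate transporter gene H16_RS29270 (-6.87 ± 0.62) and the ABC transporter gene H16_RS32720 (-6.84 ± 0.40).

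Denitrification genes were lower in 6 of 22 cases (median -0.80, or -0.57 with members at 0 counts set to their bound, list adjusted p = 7.87e-11, passing too at adjusted p = 0.00573 with an estimated correlation), nosZ (H16_RS32735) at -5.51 ± 0.48. Over the denitrification list alone, 8 were lower and none higher. Lactate and pyruvate genes were lower in 5 of 14 cases (median -0.34, list adjusted p = 6.77e-07, passing too at adjusted p = 0.0322 with an estimated correlation), aceE (H16_RS06820) at -3.31 ± 0.45 and ldh (H16_RS03295) at -3.91 ± 0.43. Stationary phase genes were lower in 14 of 27 cases and higher in 2 (median -1.31, list adjusted p = 7.87e-10, adjusted p = 0.121 with an estimated correlation), H16_RS25855 at -4.60 ± 0.57. In the stationary phase list alone, 15 were lower and 2 were higher. The Calvin cycle list was lower in 4 of 6 cases (median -2.08, list adjusted p = 2.58e-07, passing too at adjusted p = 0.0231 with an estimated correlation) and terminal oxidases in 8 of 29 (median -0.05, or 0.20 without scaling, list adjusted p = 8.52e-04, adjusted p = 0.134 with an estimated correlation), ccoG (H16_RS11570) at -4.48 ± 0.40. Adjusted over the terminal oxidase list alone, 11 were lower and none higher. Ribosomal protein genes were lower in 24 of 59 cases (median -1.17, list adjusted p = 1.11e-13, adjusted p = 0.424 with an estimated correlation), rplN (H16_RS17330) at -2.09 ± 0.47. In the ribosomal list alone, 50 were lower and 1 was higher. The rplN call ended without ammonium sulfate 48 h replicate 1 (adjusted p = 0.0839). ATP synthase genes were lower in 3 of 9 cases (median -1.16, list adjusted p = 4.93e-05, adjusted p = 0.418 with an estimated correlation) and NADH dehydrogenase genes in 3 of 16 (median -0.21, or 0.06 without scaling, list adjusted p = 0.0235, adjusted p = 0.75 with an estimated correlation). Over the ATP synthase list alone, 9 were lower and none higher. Adjusted over the NADH dehydrogenase list alone, 5 were lower and none higher. The NADH dehydrogenase list did not pass without ammonium nitrate 48 h replicate 1 or ammonium sulfate 48 h replicate 1 or 3 (adjusted p from 0.0634 to 0.136). PHB synthesis genes were lower in 2 of 13 cases (median -0.16, or 0.11 without scaling, list adjusted p = 0.00455, adjusted p = 0.293 with an estimated correlation), phaP2 (H16_RS32515) at -3.45 ± 0.36 and phbB (H16_RS09985) at -3.66 ± 0.49. Sulfate uptake genes were higher in 4 of 26 cases and lower in 2 (median 0.20, list adjusted p = 0.0491, adjusted p = 0.514 with an estimated correlation), cysT (H16_RS11190) by 2.66 ± 0.48. Over the sulfate list alone, 9 were higher and 3 were lower. The sulfate list did not pass without ammonium nitrate 48 h replicate 1 or ammonium sulfate 48 h replicate 1 or 2 (adjusted p from 0.0964 to 0.151). At this time 522 genes differed, 187 higher and 335 lower, 459 at least 2-fold, and 299 without ammonium sulfate 48 h replicate 1. The other 12 lists did not pass (adjusted p from 0.146 to 0.868).

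**Figure D4:**
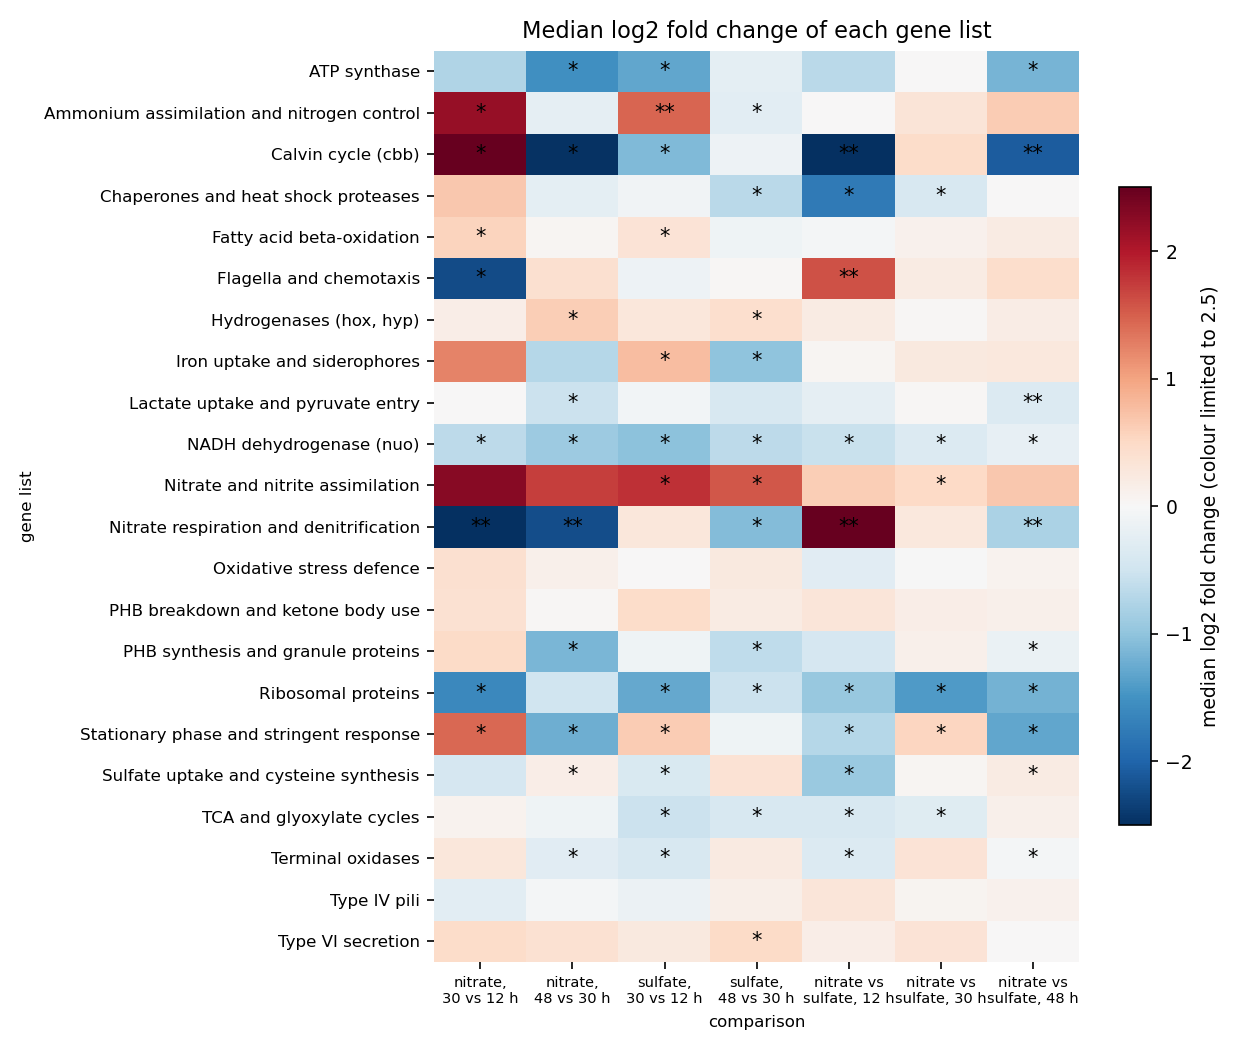
Median log2 fold change of each of the 22 gene lists in the 7 comparisons of 2 groups, with colour limited to 2.5 either way; 1 star marks a list adjusted p under the threshold and 2 stars a pass with an estimated correlation too. The Calvin cycle list holds mostly cbb3 oxidase genes, and the medians of 6 called lists change sign without scaling: lactate and terminal oxidases from 30 to 48 h in ammonium nitrate, ammonium in ammonium sulfate, and NADH dehydrogenase, PHB synthesis and terminal oxidases between sources at 48 h.

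The change from 12 to 30 h itself differed between the sources for 779 genes, 306 with a higher and 473 with a lower log2 change in ammonium nitrate, 760 of them by at least 2-fold. The cbb3 oxidase genes ccoN (H16_RS11590), ccoO (H16_RS11585) and ccoP (H16_RS11575) changed more upward in ammonium nitrate than in ammonium sulfate, by 4.86 ± 0.65, 4.57 ± 0.73 and 4.52 ± 0.64. The differences for H16_RS26885 and aceA (H16_RS11130) were 5.61 ± 0.64 and 4.40 ± 0.89. On the other side were H16_RS30305 (-7.40 ± 0.59, adjusted p = 1.45e-06), flgF (H16_RS20060, -7.09 ± 0.99), fliI (H16_RS30540, -6.55 ± 1.04), H16_RS32840 (-7.08 ± 0.78) and H16_RS30035 (-9.00 ± 1.26). By list, denitrification changes were lower in 9 of 22 cases and higher in 1 (median -4.04, list adjusted p = 7.33e-07, passing too at adjusted p = 0.0144 with an estimated correlation), and flagella changes lower in 36 of 78 and higher in 4 (median -1.71, list adjusted p = 1.27e-15, adjusted p = 0.061 with an estimated correlation). Adjusted over the denitrification list alone, 12 were lower and 4 were higher. In the flagella list alone, 39 were lower and 4 were higher. The Calvin cycle list was higher in 4 of 6 cases (median 3.48, list adjusted p = 6.27e-07, passing too at adjusted p = 0.0347 with an estimated correlation) and terminal oxidases in 5 of 29 (median 0.56, list adjusted p = 2.44e-04, adjusted p = 0.15 with an estimated correlation). Stationary phase changes were higher in 6 of 27 cases (median 0.98, list adjusted p = 7.33e-05, adjusted p = 0.378 with an estimated correlation), H16_RS25860 by 3.45 ± 0.66, and sulfate uptake changes higher in 4 and lower in 1 of 26 (median 0.79, list adjusted p = 0.00569, adjusted p = 0.378 with an estimated correlation). In the stationary phase list alone, 10 were higher and none lower. Over the sulfate list alone, 10 were higher and 1 was lower. Chaperone changes were higher in 3 of 22 cases (median 1.52, list adjusted p = 0.00532, adjusted p = 0.593 with an estimated correlation). Adjusted over the chaperone list alone, 8 were higher and 1 was lower. The other 15 lists did not pass (adjusted p from 0.159 to 0.974). The count was 362 or 384 without ammonium nitrate 12 h replicate 1 or 2, and 501 without ammonium sulfate 12 h replicate 2.

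The change from 30 to 48 h differed between the sources for 271 genes, 69 with a higher and 202 with a lower log2 change in ammonium nitrate, and 270 by at least 2-fold. In the first group hutI (H16_RS15030) was at 4.88 ± 0.31 (adjusted p = 5.08e-08), H16_RS15035 at 4.97 ± 0.35, H16_RS15025 at 4.50 ± 0.35 and urocanate hydratase (H16_RS15040) at 4.24 ± 0.39. The aldolase gene H16_RS09455 followed at 4.25 ± 1.00. The H16_RS09455 call ended without ammonium nitrate 30 h replicate 1 or 48 h replicate 3 or ammonium sulfate 48 h replicate 1 or 2 (adjusted p from 0.0502 to 0.0611). Lactate permease (H16_RS19175) was at -8.06 ± 0.70, H16_RS19180 at -7.09 ± 0.77, and the nitrous oxide reductase accessory gene H16_RS32710, the transporter gene H16_RS32720 and the maturation gene H16_RS32725 at -6.73 ± 0.40, -7.24 ± 0.48 and -6.88 ± 0.57. Denitrification changes were lower in 6 of 22 cases (median -1.38, list adjusted p = 2.53e-12, passing too at adjusted p = 0.00311 with an estimated correlation), stationary phase changes in 10 of 27 (median -1.42, list adjusted p = 1.13e-12, adjusted p = 0.0579 with an estimated correlation) and lactate changes in 5 of 14 (median -0.47, list adjusted p = 3.68e-06, passing too at adjusted p = 0.0497 with an estimated correlation). In the denitrification list alone, 10 were lower and none higher. Over the stationary phase list alone, 15 were lower and none higher. Members of the Calvin cycle list were lower in 4 of 6 cases (median -2.55, list adjusted p = 1.05e-07, passing too at adjusted p = 0.0196 with an estimated correlation), terminal oxidases in 7 of 29 (median -0.43, list adjusted p = 4.27e-05, adjusted p = 0.0579 with an estimated correlation) and PHB synthesis genes in 2 of 13 (median -0.43, list adjusted p = 0.00184, adjusted p = 0.215 with an estimated correlation), phaP2 (H16_RS32515) at -3.95 ± 0.47. ATP synthase genes, with none called (median -1.16, list adjusted p = 0.0029, adjusted p = 0.598 with an estimated correlation), and type VI secretion genes (median -0.52, list adjusted p = 0.0207, adjusted p = 0.505 with an estimated correlation) also passed as lists; in replicate 2 at 30 h the median ATP synthase gene departed by -1.26 in ammonium nitrate and -0.88 in ammonium sulfate, and the median stationary phase gene by -0.25 and 0.62. The ATP synthase list did not pass without ammonium sulfate 30 h replicate 2 (adjusted p = 0.0524). Over the type VI secretion list alone, 2 were lower and 1 was higher. The type VI secretion list missed the threshold without ammonium nitrate 30 h replicate 2 or 48 h replicate 2 or ammonium sulfate 30 h replicate 1 or 48 h replicate 1 (adjusted p from 0.0561 to 0.107). Among type VI genes tssI (H16_RS29230) was lower, at -5.05 ± 0.43. The other 14 lists did not pass (adjusted p from 0.0654 to 0.895).

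The genes of PHB turnover were followed in every comparison because the series concerns biopolymer production. The synthase gene phaC (H16_RS07135) stood at 2090.1 ± 128, 2177 ± 685 and 892 ± 292 at 12, 30 and 48 h in ammonium nitrate and at 2323 ± 88.6, 2009 ± 302 and 1217 ± 254 in ammonium sulfate; it fell from 30 to 48 h in ammonium nitrate by 1.29 ± 0.30 (adjusted p = 0.00408). The reductase gene phaB (H16_RS07145) fell from 30 to 48 h by 1.33 ± 0.25 in ammonium nitrate and by 1.14 ± 0.25 in ammonium sulfate, and the regulator gene phaR (H16_RS07150) fell by 1.14 ± 0.22 and by 1.10 ± 0.22. The thiolase gene phaA (H16_RS07140) rose by 0.81 ± 0.28 from 12 to 30 h in ammonium nitrate and fell by 0.68 ± 0.25 and by 0.85 ± 0.25 from 30 to 48 h in the nitrate and sulfate cultures. The phaA call for 12 to 30 h in ammonium nitrate ended without ammonium nitrate 12 h replicate 1 or 2 or 30 h replicate 1 (adjusted p from 0.0868 to 0.146). The phaA call for 30 to 48 h in ammonium nitrate ended without ammonium nitrate 30 h replicate 1, 2 or 3 or 48 h replicate 1 or 3 (adjusted p from 0.0597 to 0.162). The phaA call for 30 to 48 h in ammonium sulfate ended without ammonium sulfate 30 h replicate 1 or 3 or 48 h replicate 1, 2 or 3 (adjusted p from 0.05 to 0.124). At 12 h phaA was lower in ammonium nitrate at -0.93 ± 0.28. The phaA call ended without ammonium nitrate 12 h replicate 1 or 2 or ammonium sulfate 12 h replicate 1 or 2 (adjusted p from 0.0735 to 0.177). Most abundant was the phasin gene phaP1 (H16_RS06855), whose protein coats PHB granules, at 22985 ± 559.8, 21910 ± 3461 and 9591 ± 4870 in ammonium nitrate and 19709 ± 1250.2, 18401 ± 5968 and 22234 ± 12540 in ammonium sulfate; it passed in none of the 9 comparisons (adjusted p from 0.0628 to 0.984). Of 4 depolymerase genes named phaZ, H16_RS14260 rose from 12 to 30 h by 3.29 ± 0.80 in ammonium nitrate and by 2.67 ± 0.67 in ammonium sulfate. The H16_RS14260 call for 12 to 30 h in ammonium nitrate ended without ammonium nitrate 12 h replicate 1 (adjusted p = 0.0555). The H16_RS14260 call for 12 to 30 h in ammonium sulfate ended without ammonium sulfate 12 h replicate 1, 2 or 3 or 30 h replicate 2 (adjusted p from 0.0718 to 0.179). H16_RS05710 and H16_RS20440 rose over the same interval in ammonium nitrate by 0.99 ± 0.37 and by 0.87 ± 0.28, and H16_RS23825 passed in no comparison (adjusted p from 0.0721 to 0.956). The H16_RS05710 call ended without ammonium nitrate 12 h replicate 1 or 2 or 30 h replicate 1, 2 or 3 (adjusted p from 0.0583 to 0.182). The H16_RS20440 call ended without ammonium nitrate 12 h replicate 1 or 2 or 30 h replicate 3 (adjusted p from 0.0512 to 0.131). Without TMM the log2 ratios of phaA, phaC, phaB and phaR from 30 to 48 h were -0.067, -0.62, -0.69 and -0.48 in ammonium nitrate and -0.53, -0.43, -0.86 and -0.81 in ammonium sulfate. In all other comparisons these genes did not pass, with phaC closest at adjusted p = 0.123, phaB at 0.0539, phaR at 0.145 and phaA at 0.121.

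**Figure D5:**
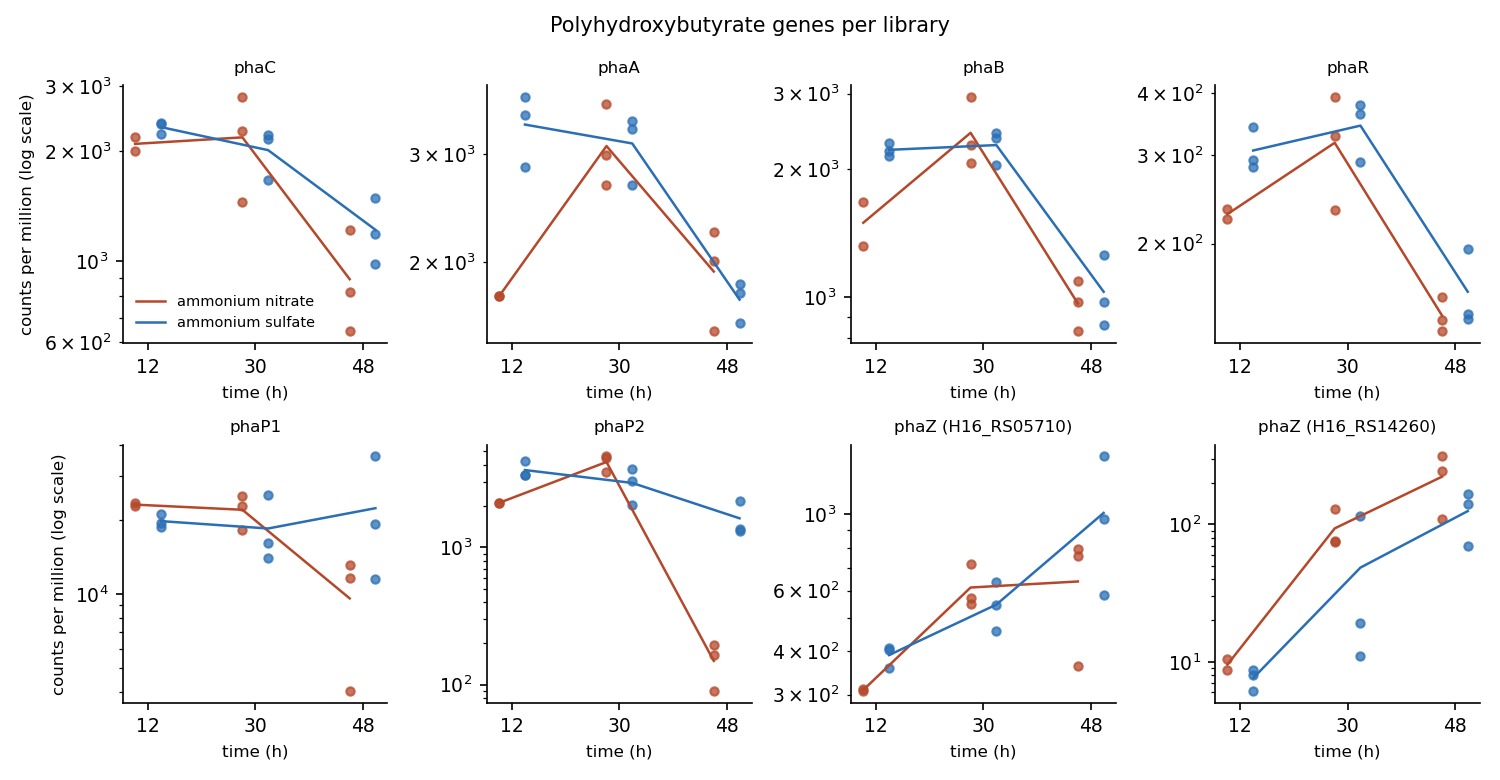
CPM on a log axis at 12, 30 and 48 h for 8 genes of PHB synthesis, granules and breakdown; points are libraries, lines join group means, and colour gives the nitrogen source. The phasin gene phaP1 is the most abundant at each time, and phaP2 is lowest at 48 h in ammonium nitrate.

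Ribosomal RNA had been removed and 15 rRNA genes together held 4 to 40 counts per library, a share of 2.54e-05 to 4.61e-04 % of all counts. Two-sided exact permutation tests of this share between sources and between times gave p from 0.1 to 1 in 7 comparisons, where 0.1 is the smallest p the design allows, and adjusted p from 0.7 to 1.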

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

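Among the tests below, the matched gene lists, the scaling without ssrA, the SD within groups and the positions of the 30 h libraries between the times were chosen after the result was seen.

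Changes over time that differed between the nitrogen sources, by a test of the difference itself, drew attention. From 12 to 30 h there were 779 such genes. The difference was 5.61 for H16_RS26885, 4.86 for ccoN, 4.57 for ccoO, 4.52 for ccoP and 4.40 for aceA. It was -9.00 for H16_RS30035, -7.40 for H16_RS30305, -7.09 for flgF, -7.08 for H16_RS32840 and -6.55 for fliI. With an estimated correlation, the Calvin cycle list, mostly cbb3 oxidase genes, passed at adjusted p = 0.0347 and the denitrification list at adjusted p = 0.0144. The 12 h ammonium nitrate group had 2 libraries, and the count fell to 362 without its replicate 1.

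From 30 to 48 h the difference between sources passed for 271 genes. It was 4.97 for H16_RS15035, 4.88 for hutI (H16_RS15030), 4.50 for H16_RS15025, 4.25 for H16_RS09455 and 4.24 for H16_RS15040. The H16_RS09455 call ended without any 1 of 4 libraries named above (adjusted p from 0.0502 to 0.0611). The difference was -8.06 for H16_RS19175, -7.24 for H16_RS32720, -7.09 for H16_RS19180, -6.88 for H16_RS32725 and -6.73 for H16_RS32710. With an estimated correlation, the Calvin cycle list passed at adjusted p = 0.0196, the lactate list at 0.0497 and the denitrification list at 0.00311. Of 100 arrangements of the source labels within each time, 7 gave as many genes or more, the real one included, and the highest of the others gave 882. Of the 6 others, 5 held the real split, or its mirror, at 30 or 48 h and so carried a difference between the sources, so the arrangements do not decide whether chance gave the count. The remaining one gave 643; it and the highest set ammonium nitrate replicate 1 and ammonium sulfate replicates 1 and 3 against the rest at 30 h, which points to a structure of the 30 h libraries other than the source.

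Ribosomal protein genes had lower medians in ammonium nitrate at 12, 30 and 48 h, -0.94, -1.41 and -1.17, but the list did not pass with an estimated correlation (adjusted p = 0.58, 0.29 and 0.424). A bias from gene length and level was argued against: of 1000 lists of other genes matched on both, none reached these medians, and the lowest were -0.75, -0.27 and -0.74. With ssrA, a small stable RNA with a large share of the counts, left out and no scaling, the ribosomal protein genes lay below all coding genes with log2 differences of -0.96, -1.44 and -1.09 at 12, 30 and 48 h; this shifts all genes of a library alike and decides nothing on ssrA as the cause. A slower growth rate in ammonium nitrate may lower these genes, but growth was not part of the data and this stays untested, as does any difference in sampling between the cultures.

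The 30 h libraries numbered 2 of both sources departed from the other 30 h libraries in a shared way, with a correlation of 0.464 across genes and with 139 genes at least 2-fold lower and 133 at least 2-fold higher in both. A 48 h sample under a 30 h label was argued against, since on a scale from the other 30 h libraries (0) to the 48 h mean (1) the library lay at 0.543 in ammonium sulfate and 0.256 in ammonium nitrate, below the lowest 48 h libraries at 0.822 and 0.888. A mixture with 48 h RNA needs the same share from rising and falling genes, and these differed by 0.386 in ammonium sulfate and by 0.420 in ammonium nitrate. Handling shared by libraries of 1 number, for which the labels give no batch, and cultures further advanced at 30 h both may explain it and were not tested.

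More genes changed from 12 to 30 h in ammonium nitrate, 2620, than in ammonium sulfate, 589. A smaller spread in ammonium nitrate could not lower the errors of that source alone, since each gene has 1 dispersion for all libraries. The median standard errors, 0.368 in ammonium nitrate and 0.327 in ammonium sulfate, followed the group sizes. Their ratio of 1.125 was near the 1.118 set by the group sizes alone, so they do not test the spread of either source. In this fit the errors were not smaller in ammonium nitrate. The SD of log2 levels within groups, at the median gene, was 0.300 and 0.378. Library size was argued against, since with each library thinned to 8017553 counts the numbers were 2609 and 575. The median absolute log2 fold change was 0.744 against 0.405; a biological effect of the source, which the design names, may underlie this and stays a hypothesis from the same data.

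For 5 counts of genes, the 6 libraries allow only 10 splits, too few for a share under 0.05. From 30 to 48 h the real split gave 2000 genes in ammonium nitrate and the highest other 0; in ammonium sulfate these were 808 and 27. From 12 to 30 h in ammonium sulfate they were 589 and 0, and between sources at 48 h 522 and 1. Between sources at 30 h the real split gave 77 genes and another 387, so that 2 of the 10 splits gave as many. That split was the 30 h arrangement named above, which again points to a structure other than the source; with the replicate number as a block in a fit of these libraries alone the count was 47.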

How the results depend on the processing

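Leaving out both 30 h libraries numbered 2, the block over 30 h libraries alone and the narrower TCA list were chosen after seeing data. Without cbb3 oxidase genes the Calvin cycle list had 2 tested members, too few for a test. Of 140 recomputed counts of genes, 110 lay within 1.5 times the reported one. In a subset of genes, picked mostly for large changes, no call changed direction in 10335 values and 1292 were lost. Members not called changed sign in 242 of 5006 and 153 gained a call. Of 2956 recomputed list results, 161 lost a call and 66 gained one.

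RLE size factors, no filter on low counts, RNA genes left out and the replicate block by title or library number kept each count within 1.5 times; with the replicate block the counts were 2600 and 2054 genes over time in ammonium nitrate, 632 and 900 in ammonium sulfate, 1316, 100 and 567 between the sources at 12, 30 and 48 h, and 826 and 275 for the differences in change. DESeq2 gave 919 genes from 12 to 30 h in ammonium sulfate and 236 between sources at 30 h. With only the compared groups in the fit, 129 genes changed from 30 to 48 h in ammonium sulfate, and 2637 and 15 differed between sources at 12 and 30 h. Leaving out both 30 h libraries numbered 2 gave 1712 genes from 30 to 48 h in ammonium sulfate and 192 between sources at 30 h, and the block over 30 h libraries alone gave 47. In these cases the cause was not tested.

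With each library left out in turn, counts ran from 1371 to 2323 genes from 12 to 30 h in ammonium nitrate and from 229 to 612 in ammonium sulfate. From 30 to 48 h in ammonium sulfate they ran from 263 to 1563, the highest without 30 h replicate 2. Between sources they ran from 528 to 1018 at 12 h, from 13 to 470 at 30 h and from 299 to 584 at 48 h. The difference in change ran from 362 to 1053 genes from 12 to 30 h. The counts from 30 to 48 h in ammonium nitrate, 1343 to 2110, and for the difference in change over that interval, 218 to 398, stayed within 1.5 times. Fewer libraries lower the power of each test, and the cause of the rises was not tested.

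Of 198 list tests, 82 passed; 14 of these passed with an estimated correlation and 55 with fry, which passed 7 others. The nitrate assimilation list, which did not pass for the difference in change from 12 to 30 h, passed in the opposite direction without ammonium sulfate 30 h replicate 2 (adjusted p = 0.0185) and without both 30 h libraries numbered 2 (adjusted p = 0.0178); with each library left out its adjusted p ran from 0.0185 to 0.975. The TCA list from 12 to 30 h in ammonium nitrate changed sign without the isopropylmalate genes and passed neither way (adjusted p = 0.768), and between sources at 30 h it did not pass without them (adjusted p = 0.0832). The cause was not tested.

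Log2 ratios of PHB gene levels from 30 to 48 h were within the spread with the deposited FPKM, and 13 of 18 moved by more than it without TMM, as all genes moved together by 0.64 in ammonium nitrate and 0.30 in ammonium sulfate. In ammonium nitrate phaA moved from -0.68 to -0.067, phaC from -1.29 to -0.62, phaB from -1.33 to -0.69, phaR from -1.15 to -0.48, and phaZ from 0.06 to 0.74 (H16_RS05710), from 1.25 to 1.91 (H16_RS14260), from 0.00 to 0.63 (H16_RS20440) and from -0.02 to 0.61 (H16_RS23825). In ammonium sulfate phaA moved from -0.85 to -0.53, phaC from -0.72 to -0.43, phaB from -1.14 to -0.86, phaR from -1.10 to -0.81 and phaZ H16_RS20440 from -0.27 to 0.084. The rRNA share stayed within the spread for each library left out.

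On simulated data of the same depth, 4-fold changes were recovered for 65.0 to 97.0 % of genes in the comparisons of 2 groups, for 12.0 % in the difference in change from 12 to 30 h and for 46.5 % from 30 to 48 h, and 2-fold changes for 0 to 17 %. Changes of 2-fold were thus often missed in the simulation, where about 100 genes changed at each fold. Far more genes were called in several comparisons of the data, such as 2620 from 12 to 30 h in ammonium nitrate. A larger number of changed genes eases the adjusted threshold, so these shares need not hold for the data.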

Other observations

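The test of ssrA here was chosen after its values were seen.

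The small stable RNA ssrA (H16_RS33880) held 10.8 to 34.2 % of the counts of a library. Its mean share at 12, 30 and 48 h was 22.5 ± 4.20, 26.3 ± 5.96 and 28.7 ± 8.67 % in ammonium nitrate and 12.0 ± 1.12, 19.0 ± 5.86 and 21.9 ± 4.03 % in ammonium sulfate (SD, n = 2 for ammonium nitrate at 12 h and 3 otherwise). The mean difference between sources was 8.20 percentage points (exact permutation p = 0.008, 4000 arrangements of labels within each time). This p takes the times as independent, which fails if cultures were sampled repeatedly. The 7 tests between pairs of groups gave adjusted p from 0.56 to 0.8.

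Between sources, departures from group means correlated at 0.229 to 0.464 at 30 h and -0.213 to 0.165 at 48 h for same-numbered libraries. Of 3 ammonium nitrate libraries, 2 at 30 h and 1 at 48 h correlated best with the same number. Of the Calvin cycle genes, 18 did not pass the count filter, with at most 62 counts over 17 libraries. The permease gene ntrB is in the nitrate assimilation and ammonium lists, and the ribosomal list holds the methyltransferase gene prmB. The hydrogenase list holds formate (fdhD, fdhE) and xanthine (xdhA, xdhC) dehydrogenase genes and a succinate dehydrogenase assembly gene (H16_RS13085).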
